A study of Homo sapiens with 4 samples.

How the data were processed

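Total RNA of MDA-LM2 cells, a derivative of the human breast cancer line MDA-MB-231 selected for colonising the lung of mice, was measured on 4 Illumina expression BeadChip arrays. Per the labels' protocols, cells were transfected with siRNA against SOX4 or with control siRNA using a lipofection reagent, RNA was taken 48 h later, and it was labelled with biotin for a single-colour array. The titles put 2 arrays in the siSOX4 group and 2 in the siControl group. The series' design text says that 2 siRNAs against SOX4 were used, but the labels do not say whether the sample numbers are the siRNAs, so the arrays are called siSOX4 sample 1 and siSOX4 sample 2. Nothing says that samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. In the siSOX4 group that spread may also hold a difference between the 2 siRNAs.

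The deposited signal table holds, per the file headers, an intensity and a detection p-value for each of 47323 probes on each array. The intensities are on a linear scale, with medians of 82.0 and 76.6 for siSOX4 samples 1 and 2 and 82.4 and 78.6 for siControl samples 1 and 2, and the values show no background subtraction and no scaling between arrays. Each detection p-value column never increases with the deposited signal of its own array, while it does with that of any other array, which ties the 4 unnamed columns to their arrays. The scanner software is not given in the sources used here. The deposited series matrix holds ratios of each signal to its array's median over all probes, on a linear scale, which was found by recomputing them from the signal table. The authors' deposited fold table holds 1 ratio per accession. For 100% of the 16367 probes that an accession matched uniquely, that ratio equalled the mean of the siControl columns over the mean of the siSOX4 columns of the series matrix, within a relative tolerance of 1e-06, so a ratio above 1 means a lower signal after siSOX4.

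Signals were background-corrected and normalized with limma 3.58.1 (neqc: normexp with negative-control statistics inferred from the detection p-values, an offset of 16, quantile normalization, log2) in R 4.3.3. Probes with a detection p-value under 0.05 on at least 2 of the 4 arrays were kept, 20118 in all. Gene symbols came from the platform annotation. Of the 47323 probes, 30113 had 1 symbol, 8 had several and 17202 were not listed and stay unnamed here. Of the kept probes, 14970 had 1 symbol and 5148 were unnamed; no symbol needed updating through its gene ID. Each of 11389 genes was represented by its kept probe of highest mean signal.

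The comparison was siSOX4 minus siControl in limma (lmFit, then eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over all kept probes and a threshold of adjusted p under 0.05. Errors given after ± are limma's standard errors of the difference, with n = 2 arrays per group. An exact permutation test of 2 against 2 cannot give a p below 0.333, so none was used. A gene detected on no array of a group has only a bound there, given as "at least N-fold": the brighter group's mean against, on each array of the dim group, the higher of the lowest signal among detected probes and the probe's own signal, as means of normalized log2 values. For genes with close paralogs (the AKR1B and AKR1C families and the histone genes), a probe may also bind the related transcripts, so their values are uncertain as to the member.

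Gene lists, 36 in all, were written from general knowledge of pathways, cell types and reported SOX4 targets, and like the samples, tests and first set of alternatives they were fixed before the data were examined. Lists were tested with limma's camera (preset correlation 0.01, adjusted over the 36 lists), with camera using an estimated correlation, and with fry; counts of members "adjusted over the list alone" use Benjamini-Hochberg within the list. Genes named in the text are SOX4, the measured reported SOX4 targets and miR-335 metastasis genes, the 12 genes per direction of largest change past the threshold, filled where fewer pass with those of smallest p that lay on 1 side of both controls on both siSOX4 arrays and have an ordinary gene symbol, and 2 to 4 members of largest change in each list described. Further genes are named only where the text says that they were chosen after their values were seen.

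The fits and list tests were tested on simulated arrays built on the 20118 kept probes of the siSOX4 and siControl comparison, in 20 simulations. At the threshold used, 0.448% of 1.5-fold changes, 13.7% of 2-fold changes and 90.6% of 4-fold changes were recovered, with 3.05 false calls per simulation. Both simulated groups had the same spread, and the number of changed probes was set by hand. In the real arrays the log2 difference had an SD of 0.43 between the siSOX4 samples and 0.26 between the controls. The simulated rates therefore need not hold for the real arrays, where ABCA1 (4.67-fold) and AKR1B10 (7.01-fold) did not pass. A list shifted by 0.5 on the log2 scale was called in 20 of 20 simulations, and 1 of 720 unchanged lists was called. With an estimated correlation the shifted list had p under 0.05 in 20 of 20 simulations, in which genes varied independently of each other. The number of arrays limits the precision. Alternatives covered the background correction, normalization, source of values, detection filter, replicate number as a block, variance model, choice of probe, threshold, list test and leaving out each array. A slide was named nowhere, so no slide block was fitted.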

Results

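SOX4 is a transcription factor of the SoxC group and a target of the metastasis-suppressing microRNA miR-335. The comparison asks which transcripts of metastatic MDA-LM2 breast cancer cells depend on it. Transcripts were measured 48 h after transfection of SOX4 siRNA (2 samples) or control siRNA (2 samples). On siSOX4 samples 1 and 2, 19655 and 20292 of 47323 probes were detected, and on siControl samples 1 and 2, 18609 and 19346. The controls resembled each other more than the siSOX4 samples did. Over the kept probes the log2 difference between the 2 controls had an SD of 0.26 (Pearson r = 0.9925 across probes), against 0.43 between the 2 siSOX4 samples (r = 0.9789), and 364 genes were more than 2-fold apart between the siSOX4 samples, against 10 between the controls.

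SOX4 itself was measured by 1 annotated probe, detected on every array. Its signal was lower in both siSOX4 samples, by 0.27 and 0.44 on the log2 scale against the control mean, though not by enough to pass the test. The difference was -0.35 ± 0.19 log2 units (adjusted p = 0.487, limma), which is 21.7% less signal. The 95% interval ran from -0.80 to 0.09, so the data allow a reduction of up to 1.74-fold, and 1588 genes had a larger fold decrease than SOX4. The raw SOX4 intensities were 206 and 193 in the siSOX4 samples and 253 and 239 in the controls, 2.96 to 3.61 times the mean of the inferred negative controls. In the authors' deposited table the SOX4 ratio of siControl to siSOX4 was 1.22.

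Across the transcriptome, the genes that separated the siSOX4 samples most from the controls included lower ABCA1, the cholesterol exporter, lower aldo-keto reductase AKR1B10, and higher ANGPTL4, a secreted inhibitor of lipoprotein lipase. Unnamed probes were left out of the named genes, among them the kept probe of smallest p (2.45 ± 0.23 log2 units, ILMN_1715748). No gene passed the threshold: of 11389 genes, 0 had an adjusted p under 0.05 in limma, the smallest being 0.0675. At an adjusted p under 0.10 there were 44 genes, 20 higher and 24 lower after siSOX4, and 1689 genes had an unadjusted p under 0.05 where 569 would be expected by chance. In 47.7% of genes both siSOX4 samples lay on 1 side of both controls, where chance gives 33.3%. Leaving out siSOX4 sample 1 or 2 gave 1333 and 2762 genes, because the lone remaining sample is then assumed to vary like the controls.

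Among the genes with lower signal, named by smallest p and none past the threshold (adjusted p from 0.0675 to 0.0968, limma), ABCA1 differed by -2.22 ± 0.22 log2 units, or 4.67-fold. AKR1B10, whose probe may also bind its close paralog AKR1B15, differed by -2.81 ± 0.31. RAP1GAP, which inactivates the small GTPase Rap1, differed by -2.23 ± 0.29, and KYNU, the kynureninase of tryptophan breakdown, by -2.11 ± 0.31. TRIML2 (-1.51 ± 0.16) and EEIG1 (-1.52 ± 0.18) were nearly equal in both siSOX4 samples, and a second kept probe of EEIG1 gave -0.90. The sulfiredoxin gene SRXN1 differed by -1.22, PGD of the pentose phosphate pathway by -1.04, the endocytic adaptor SH3KBP1 by -1.20 and the EGFR inhibitor ERRFI1 by -0.90. AKR1B15 was at least 2.55-fold and TMEM144 at least 2.33-fold lower, each detected in both controls and in neither siSOX4 sample. These bounds hold for the background correction used, and without it they were 1.66-fold and 1.56-fold. AKR1B10, at 7.01-fold, was 4.11-fold without background correction.

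On the higher side, again named by smallest p with none past the threshold (adjusted p from 0.081 to 0.0968, limma), ANGPTL4 differed by 2.03 ± 0.30 log2 units, or 4.08-fold. The Arf GTPase-activating protein gene ASAP3 and CDKN3, a phosphatase acting on cyclin-dependent kinases, both differed by 1.82 (SE 0.27). SPDEF, an ETS transcription factor detected on only 1 of 2 controls, differed by 1.70 ± 0.22. The adhesion molecule gene ALCAM differed by 1.40 ± 0.17 and the transglutaminase gene TGM2 by 1.16 ± 0.14. NMNAT2 of NAD synthesis (1.55), PNMA2 (1.53), LSM14A (1.40), SCAMP1 (1.36) and IPO11 (1.12) were also higher in both siSOX4 samples than in both controls. Other kept probes gave smaller values for SCAMP1 (0.47 and 0.32) and ANGPTL4 (1.68 and 1.39). PANK3, a pantothenate kinase of coenzyme A synthesis, was at least 2.76-fold higher and was detected in neither control, with a bound of 1.75-fold without background correction. ASAP3 and SPDEF, at 3.52-fold and 3.26-fold, were 2.30-fold and 1.94-fold without it.

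**Figure D1:**
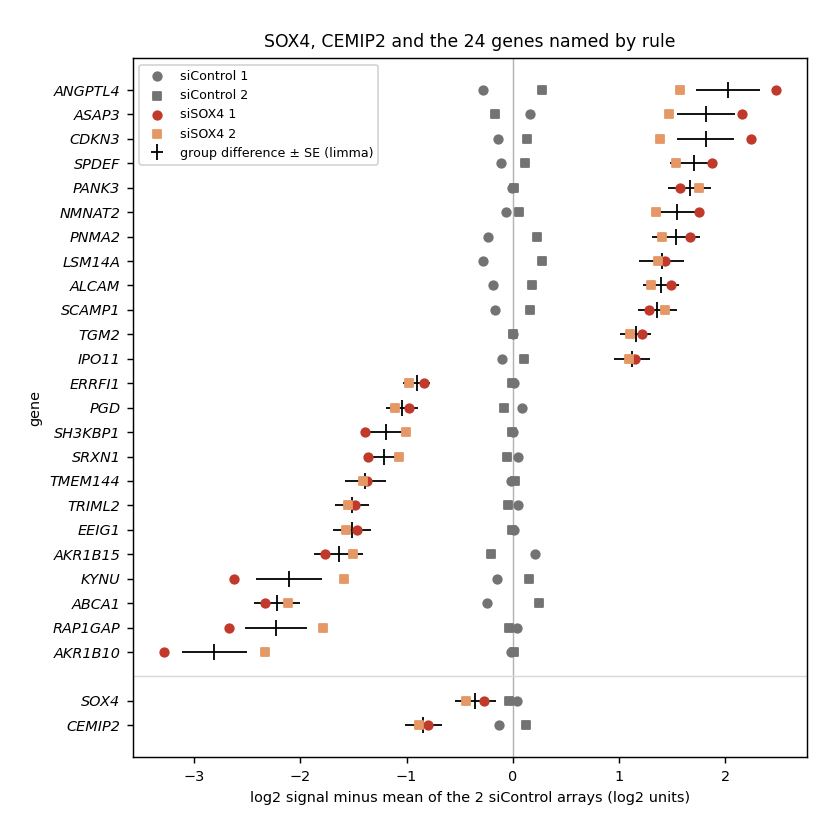
Log2 signal of each array minus the mean of the 2 siControl arrays (x axis, log2 units) for SOX4, CEMIP2 and the 24 genes named by smallest p (y axis), with siControl arrays in grey, siSOX4 arrays in red and orange, and limma's group difference ± SE as black bars. AKR1B10 is the lowest at -2.81 and ANGPTL4 the highest at 2.03, while the SOX4 probe differs by -0.35.

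Of the reported SOX4 targets, 9 of 10 were measured. CEMIP2 (also called TMEM2), a cell-surface hyaluronidase, was 1.79-fold lower, with -0.80 and -0.89 in siSOX4 samples 1 and 2. Its difference of -0.84 ± 0.18 log2 units did not pass over all genes (adjusted p = 0.151, limma). CEMIP2 was the 1 member past the threshold adjusted over the list alone (0.0136). Which data led to its report as a target was not checked. It may have entered the list through these same arrays, so this is not independent support. The histone methyltransferase gene EZH2 differed by 0.68 ± 0.25, with 1.03 in siSOX4 sample 1 and 0.32 in sample 2. EGFR differed by -0.66 ± 0.20, EDN1 by 0.48 and TUBB3 by -0.41, and DICER1 (-0.17), TEAD2 (0.13), SEMA3C (0.11) and FZD5 (0.04) differed by less than their standard errors. The list as a whole did not pass (adjusted p = 0.808, camera), and its median was 0.04 while its mean was -0.07 and the test's direction was down. For EGFR, a second kept probe gave -0.07. The miR-335 metastasis genes TNC (0.39 ± 0.29, with -0.06 and 0.83 in siSOX4 samples 1 and 2), MERTK (0.17 ± 0.20) and PTPRN2 (0.08 ± 0.21) did not pass either (list adjusted p = 0.547). Among hyaluronan genes, CEMIP2 and UGDH, which makes the hyaluronan precursor UDP-glucuronate (-1.03 ± 0.24), were lower adjusted over the list alone (2 of 8), with 0 of 8 over all genes and a list adjusted p of 0.972. In the list of other SOX factors, 0 of 6 measured members passed over all genes or adjusted over the list alone.

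Cell cycle genes were higher after siSOX4. In the group difference all 30 genes of the G2/M and mitosis list were higher, with a median log2 difference of 0.58, though in siSOX4 sample 2 24 were higher and 6 lower. The list passed camera (adjusted p = 2.64e-10, but adjusted p = 0.727 with an estimated correlation, which was 0.79). The mitotic kinesin KIF20A differed by 1.43 ± 0.39 (2.12 and 0.73 in siSOX4 samples 1 and 2), the spindle midzone protein PRC1 by 1.23 ± 0.25 and the centromeric histone CENPA by 1.08 ± 0.31. The list's median was 1.00 in siSOX4 sample 1 and 0.22 in siSOX4 sample 2, and the controls differed from each other by 0.12. Members past the threshold numbered 0 over all genes and 1 adjusted over the list alone, PRC1. In the G1/S and DNA replication list, 22 of 27 genes were higher (median 0.30), including TYMS (0.92 ± 0.27) and CCNE1 (0.76 ± 0.22, with a second probe at 0.07), with camera adjusted p = 0.000248, or adjusted p = 0.727 with an estimated correlation, and 0 members passed either way. Without siSOX4 sample 1 this list had an adjusted p of 0.0827 and did not pass.

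The histone genes measured are mostly replication-dependent ones, and 10 of 11 were higher, with a median of 0.64 (camera adjusted p = 7.51e-05, or adjusted p = 0.727 with an estimated correlation). H2AC18 differed by 1.04 ± 0.36, H2AC6 by 0.87 ± 0.24 and H2BC5 by 0.84 ± 0.20. Adjusted over the list alone 7 were higher, and over all genes 0. The median was 0.90 in siSOX4 sample 1 and 0.39 in siSOX4 sample 2, and the 2 controls differed by -0.36 (sample 1 minus sample 2), so the controls were nearly as far from each other as siSOX4 sample 2 was from their mean.

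The list of ER stress and ATF4 targets was lower as a whole, though its members did not all go the same way. Of 24 measured, 17 were lower, with a median of -0.25 (camera adjusted p = 0.00558, or adjusted p = 0.727 with an estimated correlation, which was -0.02). The asparagine synthetase gene ASNS differed by -0.94 ± 0.21, the cystine transporter gene SLC7A11 by -0.85 ± 0.20, the pseudokinase gene TRIB3 by -0.72 ± 0.22 and EDEM1 of ER-associated degradation by -0.71 ± 0.17. The ER chaperone genes HSPA5 (0.41 ± 0.17) and CALR (0.35 ± 0.15) were higher in both siSOX4 samples, as were HSP90B1 (0.12), DDIT3 (0.12) and ATF3 (0.15); these 5 were picked after their values were seen and none passed. Members lower past the threshold numbered 7 adjusted over the list alone and 0 over all genes. The medians were -0.18 and -0.33 in siSOX4 samples 1 and 2. Without siSOX4 sample 2 the list did not pass (adjusted p = 0.114).

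Genes of the Hippo pathway's YAP and TEAD factors were higher, 16 of 20 with a median of 0.31 (camera adjusted p = 0.00163, or adjusted p = 0.727 with an estimated correlation). The LIM protein gene AJUBA differed by 1.22 ± 0.22 and the tissue factor gene F3 by 1.02 ± 0.20, and these were the 2 that passed adjusted over the list alone, with 0 over all genes. Cholesterol synthesis genes were higher as well, 15 of 16 with a median of 0.40 (camera adjusted p = 0.00737, or adjusted p = 0.727 with an estimated correlation), including DHCR7 (0.67 ± 0.34) and ACAT2 (0.65 ± 0.18), while INSIG1, which restrains the pathway, differed by -0.64 ± 0.20. None of the 16 passed either way. Both lists rested on siSOX4 sample 1, without which their adjusted p was 0.145 and 0.503. By fry, 0 of the 36 lists passed, the smallest adjusted p being 0.291.

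**Figure D2:**
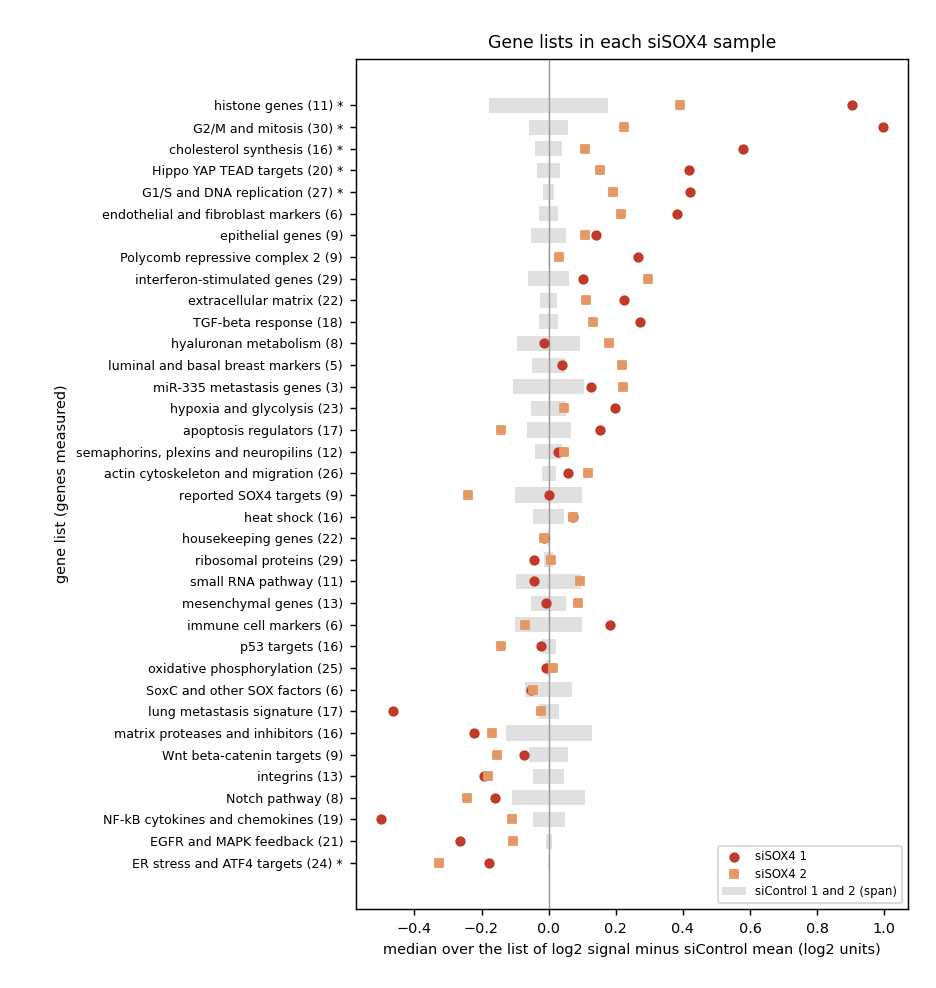
Median over each gene list (y axis, with the number of genes measured) of the log2 difference from the mean of the 2 siControl arrays (x axis, log2 units) in siSOX4 sample 1 (circles) and siSOX4 sample 2 (squares); grey bars span the medians of the 2 controls around their mean, and asterisks mark the 6 lists past camera. The G2/M list lies at 1.00 and 0.22 and the ER stress and ATF4 list at -0.18 and -0.33.

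The lung metastasis signature, genes that mark breast cancer cells homing to the lung, moved in both directions and did not pass as a list (17 measured, camera adjusted p = 0.808). The list test takes all members in 1 direction. Members that mark such cells by a low level would offset the others. Adjusted over the list alone, 3 genes were higher and 4 lower, and over all genes 0. Those of largest difference were KYNU (-2.11 ± 0.31), ANGPTL4 (2.03 ± 0.30), the EGFR ligand gene EREG (-1.78 ± 0.36, with -2.40 and -1.17 in siSOX4 samples 1 and 2) and LY6E (0.76 ± 0.16). Hypoxia and glycolysis genes did not pass as a list (adjusted p = 0.644, camera), and 0 of 23 passed over all genes. ANGPTL4 was higher and the glucose transporter gene SLC2A3 (-0.98 ± 0.20) lower adjusted over the list alone. ALDOC differed by 1.27 ± 0.39, with 1.925 and 0.62 in siSOX4 samples 1 and 2.

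Lists of secreted and immune signalling genes came close to the threshold in camera with its preset correlation, and their calls depended on single arrays. Interferon-stimulated genes had a median of 0.23 (adjusted p = 0.0828), with 18 of 29 higher and 11 lower. ISG15 (0.72 ± 0.17) and IFIT2 (0.66 ± 0.16) had the largest differences and were the 2 past adjusted over the list alone. IFI44L, next in size, went the other way (-0.56 ± 0.31). TGF-beta response genes had a median of 0.22 (adjusted p = 0.089), with 15 of 18 higher, 3 lower and 0 past adjusted over the list alone. Those of largest difference were IL11 (2.83 ± 0.79), SMAD6 (0.60 ± 0.23) and, in the other direction, BHLHE40 (-0.59 ± 0.18). The IL11 fold was 7.10, or 4.12 without background correction. NF-kB cytokine and chemokine genes had a median of -0.19 (adjusted p = 0.089, camera), with 14 of 19 lower, 5 higher and 0 past adjusted over the list alone. IL1A (-1.69 ± 0.44) and RELB (-0.76 ± 0.29) had the largest differences. In siSOX4 samples 1 and 2 IL1A differed by -2.46 and -0.91, and RELB by -1.19 and -0.32. The interferon list passed without siSOX4 sample 1 (0.0011) or siControl sample 2 (0.0317), the TGF-beta list without siSOX4 sample 2 (0.00351), and the NF-kB list without siSOX4 sample 2 (0.00351) or siControl sample 1 (0.00593). With an estimated correlation, the camera adjusted p on all arrays was 0.772 for the interferon list and 0.727 for each of the TGF-beta and NF-kB lists. No member of the 3 lists passed over all genes.

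Adhesion and cytoskeleton genes did not pass as lists. Among integrins (adjusted p = 0.181), ITGB4 (-0.91 ± 0.25) and ITGA2 (-0.83 ± 0.23) were lower adjusted over the list alone, and ITGA5 differed by -1.27 ± 0.50 (-2.20 and -0.34 in siSOX4 samples 1 and 2). Among actin and migration genes (adjusted p = 0.243), the myosin light chain kinase gene MYLK (1.43 ± 0.25) and the smooth muscle protein gene TAGLN (0.95 ± 0.20) were of largest difference, and 2 members were higher and 1 lower adjusted over the list alone. Of the matrix proteases and inhibitors (adjusted p = 0.61), 2 were higher and 3 lower adjusted over the list alone, among them PLAT (0.98 ± 0.19) and CTSL (-0.83 ± 0.17). The mesenchymal list had a median of -0.00027 (adjusted p = 0.808, camera), with ITGA5 and ZEB1 (-0.68 ± 0.21) of largest difference. The epithelial list had a median of 0.27 (adjusted p = 0.549, camera), with 6 of 9 genes higher. Among these were KRT7 (0.66 ± 0.22) and MUC1 (0.60 ± 0.43, with 0.11 and 1.08 in siSOX4 samples 1 and 2), while CLDN7 differed by -0.83 ± 0.25. In both lists 0 members passed adjusted over the list alone. In all these lists 0 members passed over all genes.

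The remaining 12 lists did not pass (adjusted p from 0.181 to 0.867). Among p53 targets, the DNA repair gene DDB2 (1.14 ± 0.23) was higher and TP53I3 (-0.83 ± 0.20) and the death receptor gene TNFRSF10B (-0.61 ± 0.15) lower adjusted over the list alone. Adjusted in the same way, JARID2 of Polycomb repressive complex 2 differed by -1.12 ± 0.17, the Notch target HEY1 by -0.77 ± 0.21 (a second probe gave 0.23), and TNRC6A of the small RNA pathway by 0.95 ± 0.19. EREG was the 1 member past the threshold adjusted over the list alone among EGFR and MAPK feedback genes, and XBP1 (-0.71 ± 0.14) and EGFR were the 2 among luminal and basal breast markers. The lists of extracellular matrix, heat shock, Wnt target, apoptosis, oxidative phosphorylation and semaphorin genes had 0 such members, and over all genes no member of the 12 lists passed.

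Genes not tied to the design gave the background. Ribosomal protein genes (29 measured) had a median of 0.01 and housekeeping genes (22 measured) one of 0.02, and markers of immune cells (6 measured, adjusted p = 0.808) and of endothelial cells and fibroblasts (6 measured, adjusted p = 0.229) did not pass. Of the latter, PDGFRB was at least 1.73-fold higher (1.33-fold without background correction) and passed adjusted over the list alone.

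The 2 siSOX4 samples differed from the controls in similar but unequal ways. Across 11389 genes, which are not independent replicates, their differences from the shared control mean correlated at r = 0.489 (Spearman 0.44, 65.3% with the same sign). In 100 simulated sets with no effect and with shared controls of a simulated spread, r was 0.333 and 60.8% had the same sign. With a different control for each sample, so that none was shared, r was 0.434 for samples of the same number and 0.316 for the crossed numbers. The simulated r of 0.333 arises from sharing controls, so it is no yardstick for these values. With the shared control mean the covariance was 0.0851 against a simulated 0.0235, a difference of 0.0616. The spread between the 2 controls alone gave 0.0151, so the simulated sets overstate what sharing these controls adds. Genes far apart between the siSOX4 samples, chosen after their values were seen, included the cytokine gene IL11 (4.32 in sample 1 and 1.34 in sample 2), ALOX5AP (3.18 and 0.68), ITGA5 (-2.20 and -0.34) and NINJ1 (-2.21 and -0.24).

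**Figure D3:**
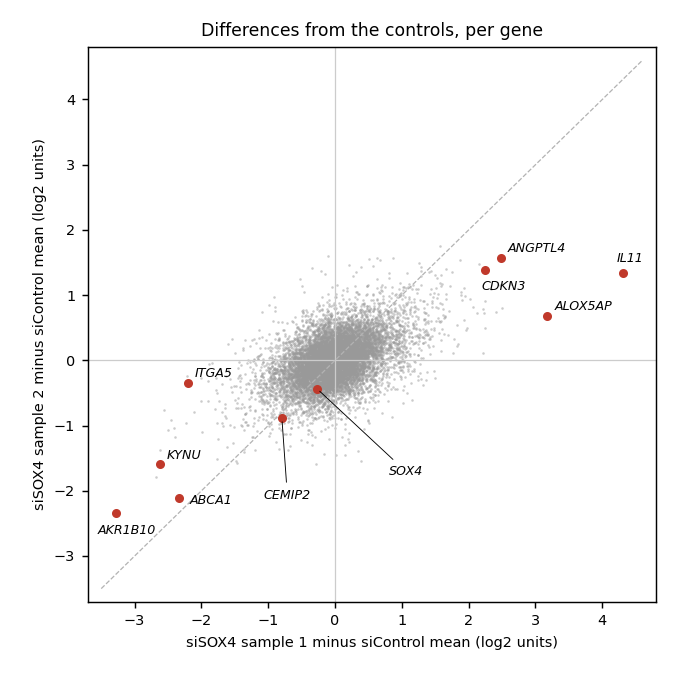
Log2 difference from the mean of the siControl arrays in siSOX4 sample 1 (x axis) and siSOX4 sample 2 (y axis), both in log2 units, 1 grey point per gene (11389), with named genes in red and the line of equality dashed. The points slope upward (r = 0.489), and IL11 (4.32 and 1.34) and ALOX5AP (3.18 and 0.68) lie far from the line.

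The authors' deposited table of ratios held 43961 rows. Over 8241 kept probes matched to it, its log2 ratios, turned to siSOX4 over siControl, correlated with the re-fitted differences at r = 0.975 (Spearman 0.986), and 96.2% had the same sign. Their SD was 0.76 of that of the re-fit, and the deposited ratios carry no background subtraction. A ratio of at least 1.5 in the authors' deposited table, meaning lower after siSOX4, was held by 347 rows, and 381 rows had a ratio of at most 1 over 1.5. In the authors' deposited table AKR1B10 stood at 4.07, KYNU at 3.90, ABCA1 at 3.89, CEMIP2 at 1.75, and CDKN3 at 0.298.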

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

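The comparison with controls of different numbers, the lists without shared genes and the bounds under other background corrections were added after the data were seen; the other alternatives were set beforehand. The SOX4 difference kept its sign and stayed short of the threshold under every alternative run. The count of genes past the threshold stayed at 0 without background correction, with an offset of 50, with median scaling, with the stricter detection filter, with both other variance models, and with the mean of a gene's probes. Over probes 0 passed in the main fit as well, so adding a 1.5-fold minimum could only leave 0. The count of genes was 1 with the series matrix values and 77 without a detection filter, where the cause was not tested, and 44 with an adjusted p under 0.10, a looser threshold. Leaving out 1 array gave 0 to 2762 genes; the high counts came without siSOX4 sample 1 (1333) or 2 (2762), when the lone sample is assumed to vary like the controls. With the replicate number as a block, 133 genes passed; the samples only share a number, and the deviations of same-numbered samples correlated at 0.11. The 44 genes were among those called without a filter and with the block. Of the 6 gene lists, 0 passed with an estimated correlation and 0 by fry. For the 5 higher lists the estimated correlation was 0.16 to 0.87, above the preset 0.01. For the ER stress and ATF4 list it was -0.02, so a correlation above the preset was not the reason there. That list's unadjusted camera p was 0.00078 with the preset and 0.065 with the estimate, and the reason was not tested. Under the other alternatives 4 to 8 lists passed, and the 6 were among them except without a siSOX4 sample. The agreement of the siSOX4 samples was r = 0.316 with crossed controls, which removes the shared control. No direction that passed a test was turned by an alternative. The slide block and the mean of SOX4 probes gave no value, as no slide is named and SOX4 has 1 annotated probe. Signals near background limit folds: of the 24 genes named by smallest p, 6 had a fold over 1.5 times smaller without background correction. The plain log2 ratios in the authors' deposited table had a smaller spread (SD ratio 0.76), though not every single ratio was smaller.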

Other observations

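The 3 tests on NRF2 targets were set before the members of that list were looked up, while the list itself was drawn up after the genes of smallest p were seen. The tests on mitotic genes and on the SOX4 probe were chosen after their results were seen.

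Several of the genes of smallest p are targets of NRF2, the transcription factor of the antioxidant response. Besides AKR1B10, SRXN1 and PGD, the aldo-keto reductase genes AKR1C2 (-1.98 ± 0.31, with other probes at -0.33 and -0.11) and AKR1C3 (-1.72 ± 0.37) were lower, as was UGDH (-1.03), so that all 8 measured genes of the group that prompted the question were lower, with a median of -1.68. Of 24 further NRF2 targets outside that family, 20 were measured and 18 were lower, with a median of -0.48, and medians of -0.64 and -0.34 in siSOX4 samples 1 and 2 against a difference of 0.01 between the controls. PIR differed by -1.14 ± 0.21, GCLC of glutathione synthesis by -1.08 ± 0.21, the glutathione reductase gene GSR by -0.92 ± 0.21 (a second probe gave 0.24) and TKT by -0.75 ± 0.21. NQO1, a standard NRF2 target, differed by -0.19 ± 0.19, and NFE2L2, which encodes NRF2, by -0.39 ± 0.15 (adjusted p = 0.339, limma). SLC7A11, at -0.85, is also in the ATF4 list, while HMOX1, another standard NRF2 target, was left out of this list and sits in the heat shock list, where it differed by 0.54 ± 0.49, with -0.34 and 1.42 in siSOX4 samples 1 and 2. With HMOX1 in and SLC7A11 out, a choice made after both values were seen, 17 of 20 genes were lower with a median of -0.43 (p = 0.121 with an estimated correlation). None of the 20 passed over all genes, and the list gave p = 3.21e-08 in camera but p = 0.0945 with an estimated correlation.

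The lower signal was not limited to aldo-keto reductases, whose probes may bind each other's transcripts. The 20 measured NRF2 targets outside that family had a median of -0.48, at percentile 0 of 10000 random lists matched on mean signal. Cross-hybridisation within the family cannot reach those genes, so their values do not measure it. Whether the lower aldo-keto reductase signals come from separate transcripts was not tested. The choice among the normalizations tried does not account for the lower median of the genes outside the family, as the highest median over the 4 others was -0.407. The median of these genes was below the control mean in both siSOX4 samples, and the higher of both samples' percentiles was 0.01. The difference between the 2 controls lay at percentile 57.8. Random lists treat genes as independent, which co-regulated genes are not, and do not measure the spread of this list between arrays. They therefore do not decide whether 1 siSOX4 sample alone carries the pattern. A difference in culture or transfection between the groups, or an off-target effect of the siRNA, was not tested and stays open. The activity of NRF2 itself was not tested.

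The higher mitotic genes did not depend on the choice among the normalizations tried, since the lowest median of the G2/M list over the 4 others was 0.491. Whether siSOX4 sample 1 alone carries the pattern cannot be told apart from an effect in both samples. Both samples lay at percentile 100 of matched random lists, but so extreme a place was also nearly reached by the difference between the 2 controls (percentile 99.9), and without siSOX4 sample 1 the list still passed camera with its preset correlation (median 0.22, adjusted p = 0.00253). Neither decides, as the random lists do not measure the spread of this list between arrays and the preset correlation of 0.01 lies far below the estimated 0.79. A difference in cell density or growth between the dishes may move these genes in the same way, and no label allows a test of it.

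For the SOX4 probe, the highest ratio of a siControl to a siSOX4 array after subtraction of the inferred background was 1.43. This is under the 2-fold set as the mark, so background at the level of the negative controls did not hide a 2-fold difference. The mark was set after the result was seen. Nonspecific signal of this probe itself was not measured, so the test cannot exclude that it compressed the fold. Whether the probe lies in a part of the transcript that remains after siRNA cleavage could not be decided, since 1 probe is annotated to SOX4 and the siRNA sequences were not used here. A weak knockdown at 48 h stays open.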
